A study of Mus musculus with 20 samples.

How the data were processed

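Liver RNA of 20 male mice was measured on Affymetrix single-channel arrays with biotin label, 1 array per mouse. Per the labels, the mice were wild type or MCAD-/- (medium-chain acyl-CoA dehydrogenase deficient) on a mixed BL6/SV129 background, 50 to 60 days old, and were injected with vehicle or with lipopolysaccharide (LPS, a bacterial cell wall component that provokes inflammation; 100 µg per 20 g body weight) and then fasted for 12 h. The 4 groups held 5 mice each, which the series description calls biological replicates. Groups and replicate numbers were taken from the sample labels alone.

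The deposited table holds 45101 probe sets as intensity on a linear scale. Per the submitters' processing notes the values were made with GCRMA, which corrects background, normalizes between arrays and summarises probes; its version and settings are not given in the sources used here. Because GCRMA normalizes between arrays, differences are relative to the whole array, and a general shift of all transcripts would not be visible. Values were taken to the log2 scale with no pseudocount. GCRMA pulls dim probe sets towards a floor, so folds that involve levels under 16 units depend on that floor and are given as bounds ("at least") where all 5 mice of a group lay under it. Where the dimmer group averaged under 16 units with 1 or 2 of its 5 mice above it, the fold is printed as fitted and depends on the floor too: Gm2788 and Gpr182 between genotypes with vehicle, Olig1, Acpp, Cidec and Cxcl11 between genotypes with LPS, Reg3b, Cyp7a1, Il1rn and S100a9 for LPS in wild type, and Reg3b, A2m, Tifa, Cd14, S100a8, Il1rn and Clec4g for LPS in MCAD-/-. For arrays, the number of mice limits the precision.

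Probe sets were named through the platform's annotation: 34945 had 1 gene symbol, 932 had several and were not named, and 9160 others, control probe sets left out, were not listed there and are unnamed here. Of those with 1 symbol, 34741 matched RefSeq annotation (assembly GRCm38.p6) by gene ID, and 0 symbols changed. That annotation was used only for names and for which genes neighbour each other. The 64 Affymetrix control probe sets were left out of all gene tests. Each of 18193 genes was represented by its brightest probe set over the 20 arrays, and a gene was tested if it exceeded 16 units (4 on the log2 scale) on at least 5 arrays, which left 8774 genes.

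One linear model with the 4 groups was fitted per gene with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation of the spread. Adjusted p-values are Benjamini-Hochberg values over the 8774 genes, two-sided, with a threshold of 0.05, and every adjusted p for a gene comes from this limma model. The 5 comparisons were MCAD-/- against wild type under vehicle and under LPS, LPS against vehicle in each genotype, and the interaction, which is the LPS response in MCAD-/- minus that in wild type. Of 36 gene lists fixed before the data were examined, the 32 with at least 4 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over lists. The same test with an estimated correlation served as an alternative, and its p is printed where it ended the call. The targeted gene was also compared by an exact permutation test, two-sided.

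The genes named in the text follow a rule set in advance: the 7 largest rises and 7 largest falls among genes past the threshold whose 2 groups did not overlap (for the interaction, past the threshold only), up to 3 members with the smallest adjusted p of each list past the threshold, a fixed panel of genes of glucose and fasting metabolism, and Acadm. Other genes named were picked after their values were seen, and this is said where they appear.

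The pipeline was tested on simulated data made from the real genes' means and spreads, 8774 genes with 200 changed. For MCAD-/- against wild type under vehicle, 46.3% of 1.5-fold changes, 86.6% of 2-fold changes and 100% of 4-fold changes were recovered. For the same contrast under LPS the shares were 64.2%, 85.1% and 100%. For LPS against vehicle they were 47.8%, 88.1% and 98.5% in wild type and 53.7%, 76.1% and 97.0% in MCAD-/-. For the interaction they were 13.4%, 59.7% and 93.9%, so that many small interactions would be missed. Simulated genes vary independently, which real genes do not. In the simulation 200 genes and 1 list changed, while 64% and 65.7% of the real tested genes passed for LPS. The Benjamini-Hochberg limit is looser when more genes change, so these shares do not carry over directly, least of all for LPS.

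Alternatives tried were the replicate number as a block, no filter and a stricter filter (64 units on at least 5 arrays), each probe set on its own, the mean of a gene's probe sets, each array centred on its median, a further quantile normalization, a trended and robust prior, array weights, a fit of the compared groups alone, an added 1.5-fold minimum and each mouse left out in turn. For lists, only the block, the filters, the mean of probe sets, the centring, the estimated correlation and the left-out mice were run. One alternative was chosen after seeing the data, leaving out 4 arrays that stood apart. Tests of 2 explanations, a stronger LPS response overall and a hepatocyte share that raises 3 cell types alike, replaced earlier forms after their values were known. The earlier forms, an ordinary slope (0.966) and a limit of 2 standard errors, had argued against both, and the present ones leave both open. For an acute phase reaction in wild type vehicle mice the limit first ignored the error of r and argued against it, and with that error it stays open. Plots were made with matplotlib 3.10.9 in Python 3.11.15.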

Results

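The series profiled the liver transcriptome of fasted mice that lack medium-chain acyl-CoA dehydrogenase, the mitochondrial enzyme encoded by Acadm that starts the oxidation of medium-chain fatty acids. Its title concerns hepatic carbohydrate management when metabolic demand is high. There were 5 mice in each of 4 groups: wild type with vehicle, wild type with LPS, MCAD-/- with vehicle and MCAD-/- with LPS. Between 30.27% and 32.36% of probe sets exceeded 16 intensity units on each array. The first principal component held 67.0% of the variance and separated LPS from vehicle, and the second held 12.9% and separated the genotypes. The standard deviation of the log2 difference between arrays of 1 group ran from 0.233 to 0.587, and the lowest value between groups was 0.567. No pair of arrays was identical. Wild type vehicle replicate 3 and wild type LPS replicate 4 had 3' to 5' log2 ratios of the actin control of 3.18 and 3.69, against group means of 2.13 ± 0.61 and 2.00 ± 0.96 (SD, n = 5), 2.08 ± 0.25 in MCAD-/- with vehicle and 1.65 ± 0.16 in MCAD-/- with LPS.

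The targeted gene Acadm followed the genotype labels in all 20 mice. Its single named probe set read 3106 to 4022 units in wild type mice with vehicle and 9.03 to 80.2 units in MCAD-/- mice with vehicle. The means were 11.73 ± 0.14 and 5.13 ± 1.20 on the log2 scale (SD, n = 5 each), a 97.3-fold lower level in MCAD-/- (exact permutation p = 0.00794, two-sided, the smallest that 252 regroupings allow). With LPS, wild type mice read 1450 to 2375 units and MCAD-/- mice 14.3 to 218 units, with means of 10.83 ± 0.26 and 5.38 ± 1.55, a 43.6-fold lower level (exact permutation p = 0.00794). Without MCAD-/- LPS replicate 3, which read 218 units, the log2 difference under LPS went from -5.45 to -6.04. The LPS difference of Acadm in wild type, -0.91 ± 0.56 (SE) on the log2 scale, did not pass the test that shared its spread with the MCAD-/- groups (adjusted p = 0.168) and passed in a fit of the wild type mice alone (adjusted p = 0.000145).

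**Figure D1:**
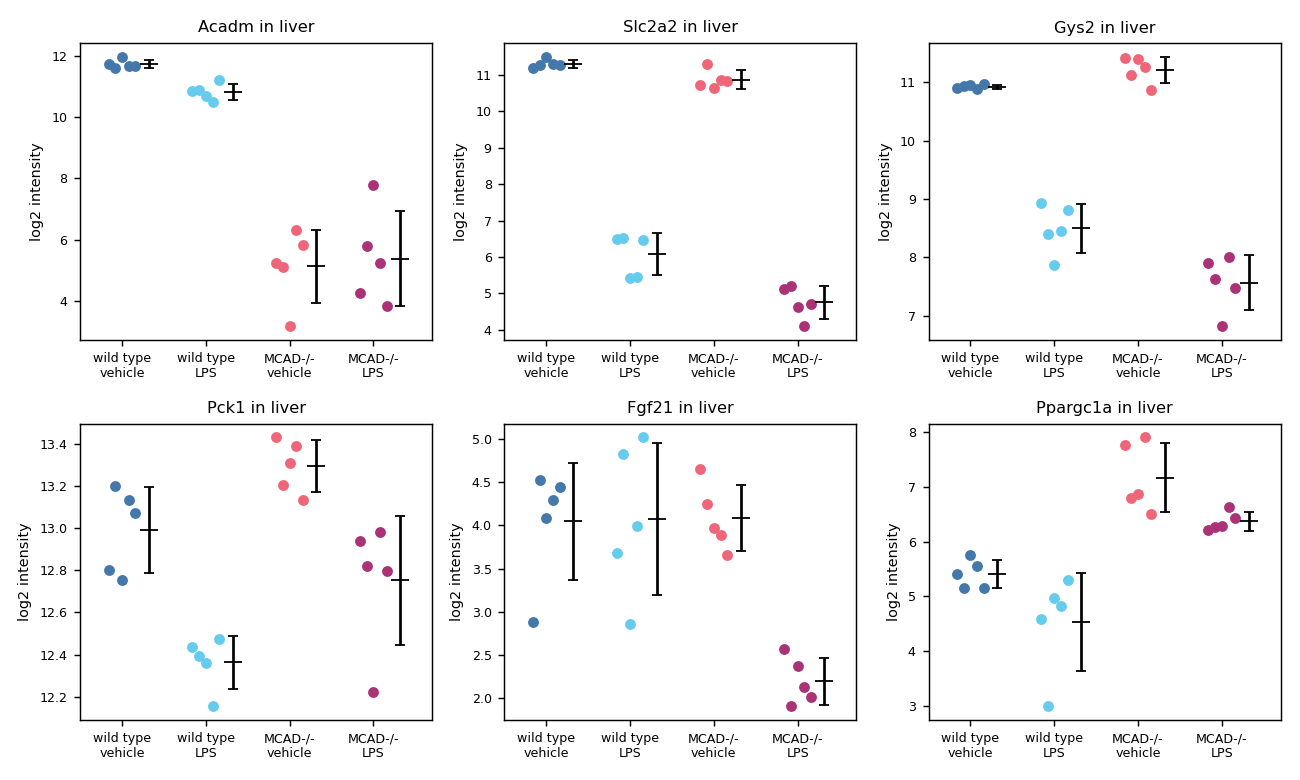
Liver expression per mouse (y axis, log2 intensity, a different range in each panel) of Acadm and 5 genes of glucose and fasting metabolism in the 4 groups on the x axis; points are mice, n = 5 per group, and the black mark with bars is the mean ± SD. Acadm lies between 1450 and 4022 units in all wild type mice and at or below 218 units in all MCAD-/- mice, while Slc2a2 falls from 2539 to 67.4 units with LPS in wild type and from 1874 to 27.0 units in MCAD-/-.

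The first comparison asked how the MCAD-/- liver differed after the fast without an inflammatory challenge. Markers of liver endothelial cells were higher in MCAD-/- mice: 13 of 15 measured members rose and 0 fell, with a median log2 change of 1.12. Clec4g, a lectin of sinusoidal endothelium, was 3.78-fold higher, Lyve1, a hyaluronan receptor, 3.63-fold, and Gpr182 2.31-fold. Of the Kupffer cell and macrophage markers 7 of 12 rose and 0 fell (median 0.88), among them the complement receptor Vsig4 (2.42-fold), the complement component C1qc (2.33-fold) and the growth factor receptor Csf1r (1.80-fold). Of the stellate cell and fibroblast markers 7 of 13 rose and 0 fell (median 0.63), with the collagen gene Col3a1 2.72-fold, Pdgfrb 1.89-fold and Angptl6 1.82-fold higher. Adjusted over the list alone, 15 endothelial, 7 Kupffer and 8 stellate members rose. The camera adjusted p was 3.69e-09 for the endothelial list and 0.000493 for each of the other 2, and adjusted p = 0.621 with an estimated correlation for all 3.

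Lipid synthesis and acute phase genes were lower in the same MCAD-/- mice with vehicle whose cell type markers were higher. Of the fatty acid synthesis list 7 of 17 members fell and 0 rose (8 adjusted over the list alone), including fatty acid synthase Fasn (2.46-fold lower), the elongase Elovl6 (2.32-fold) and acetyl-CoA carboxylase Acaca (2.01-fold). Of the cholesterol synthesis list 3 of 20 fell, which were Cyp51 (2.19-fold), Idi1 (2.56-fold) and Msmo1 (2.07-fold); adjusted over the list alone 4 fell and 1 rose. Of the acute phase proteins, which the liver secretes in inflammation, 8 of 25 fell and 0 rose (8 adjusted over the list alone). Saa4 was 2.40-fold lower, Orm3 at least 1.19-fold and the iron-binding protein Lcn2 4.91-fold lower, from 1104 to 225 units. In the same mice, MCAD-/- vehicle replicate 5 had a mean log2 level of the neutrophil markers of 5.87, with the next mouse at 3.54. The camera adjusted p was 0.0014 for fatty acid synthesis, 0.00831 for cholesterol synthesis and 0.000493 for the acute phase proteins, and adjusted p = 0.621, 0.759 and 0.759 with an estimated correlation. Per mouse, the acute phase list means overlapped, from 11.21 to 11.8 in wild type and 10.52 to 11.82 in MCAD-/-. So did the cholesterol means, from 7.05 to 8.13 and from 7.17 to 7.51. The fatty acid synthesis means did not overlap, from 9.72 to 9.75 and from 8.94 to 9.64.

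Among the glucose and fasting genes, Ppargc1a, a coactivator that drives mitochondrial and gluconeogenic genes, rose 3.37-fold in MCAD-/- with vehicle, from 42.5 to 143 units (log2 change 1.75 ± 0.33, SE; adjusted p = 0.000867), with all 5 of its probe sets past the threshold. Fbp1, an enzyme of gluconeogenesis, was 1.25-fold higher (adjusted p = 0.0123), and pyruvate carboxylase Pcx was 1.42-fold lower (adjusted p = 0.00183). The glycogen phosphorylase Pygl was 1.41-fold lower (adjusted p = 0.0329). Pck1 (log2 change 0.30), G6pc (0.50), Gys2 (0.29), Slc2a2 (-0.44), Pklr (-0.73), Pdk4 (0.71), Cpt1a (-0.25) and Fgf21 (0.04) did not pass the test, with adjusted p from 0.128 to 0.962.

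The largest single differences under vehicle were close to on or off. Clec2h, a lectin-like receptor, was at least 12.6-fold higher in MCAD-/-, Rpgrip1 at least 11.6-fold, Ugt2b38 at least 7.88-fold, the trefoil factor Tff3 at least 6.93-fold, Tmem267 at least 6.33-fold and the chemokine Cxcl13 at least 4.82-fold, and Fam47e was 17.7-fold higher. Beside Acadm, the muscle protein gene Myom2 was at least 22.3-fold lower, Gm7969 at least 10.7-fold, Cap1 at least 10.3-fold, Zfp874a at least 10.2-fold and Rad51b at least 6.63-fold, and Gm2788 was 28.8-fold lower. In all, 1422 of 8774 genes passed the threshold, 861 higher and 561 lower in MCAD-/-, and 922 of them had groups that did not overlap. Over all 8774 genes, passed or not, 1210 had groups that did not overlap, where chance gives 0.79% of genes. With each array centred on its median, 745 genes were higher and 663 lower. The background is mixed, and the sources used here do not say whether the genotypes were littermates, so strain differences are not separated from the knockout in either genotype comparison or the interaction. The calls of Acaca, Idi1, Msmo1, Lcn2 and Pygl ended in at least 1 alternative, with a highest adjusted p of 0.112, 0.0566, 0.102, 0.0816 and 0.0927, and Pck1, Pklr and Slc2a2 passed in 1 alternative each.

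The next comparison asked how the genotypes differed once LPS was added to the fast. Genes of mitochondrial fatty acid oxidation, counted without Acadm, were lower in MCAD-/-: 14 of 20 members fell and 0 rose (15 adjusted over the list alone), with a median log2 change of -0.40. Decr1, which handles unsaturated fatty acids, fell from 1071 to 551 units (1.94-fold lower), Eci1 was 1.72-fold lower and Hadh, a dehydrogenase of the pathway, 1.59-fold lower. Of the fasting-induced targets of the receptor PPARalpha 7 of 16 fell and 0 rose (9 adjusted over the list alone). The lipid droplet protein gene Cidec was 27.8-fold lower, from 432 to 15.5 units, Mgll, a monoglyceride lipase, was 2.71-fold lower, and the fasting hormone Fgf21 was at least 1.06-fold lower, from 16.9 to 4.59 units. Camera gave an adjusted p of 5.97e-05 for both lists, and adjusted p = 0.591 with an estimated correlation. Under vehicle, 3 of 20 mitochondrial oxidation genes fell in MCAD-/- (3 adjusted over the list alone) and the list did not pass (median log2 change -0.10, adjusted p = 0.0746).

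Other lists also passed between the genotypes under LPS. Of the peroxisomal and microsomal oxidation genes 8 of 16 fell (8 adjusted over the list alone), including Acot8 (2.08-fold lower) and Acaa1b (1.59-fold lower), and of the fatty acid synthesis genes 5 of 17 fell (9 adjusted over the list alone), including Acss2 (2.02-fold), Acacb (2.59-fold) and Gpam (1.80-fold). Of the amino acid catabolism and urea cycle genes 6 of 20 rose and 1 fell (7 and 1 adjusted over the list alone), with the histidine-degrading enzyme Hal 2.34-fold and Oat 1.87-fold higher. Of the immediate early genes 3 of 10 rose (4 adjusted over the list alone), Dusp1 1.97-fold, Btg2 3.92-fold and Zfp36 1.38-fold. The camera adjusted p was 0.0367, 0.00785, 0.00171 and 0.00303 for these 4 lists in turn, and adjusted p = 0.591 with an estimated correlation for each. Of the interferon-stimulated genes 6 of 28 fell and 1 rose (7 and 1 adjusted over the list alone), with Cxcl11 4.05-fold and Oas1a 2.36-fold lower and Rsad2 2.13-fold higher; the adjusted p was 0.0393, and adjusted p = 0.742 with an estimated correlation. Of the cytokine and NF-kappaB target genes 3 of 15 rose (3 adjusted over the list alone), Cxcl13 3.77-fold, Nfkbiz 1.84-fold and Tnfaip3 1.55-fold. Of the heat shock proteins 4 of 10 fell (4 adjusted over the list alone), with Hsph1 2.38-fold lower. These last 2 lists were near the threshold (adjusted p = 0.049 and 0.04995), and each had adjusted p = 0.591 with an estimated correlation. The calls of the interferon, cytokine, heat shock, peroxisomal and fatty acid synthesis lists ended in 9, 10, 9, 4 and 1 of 16 other settings, with a highest adjusted p of 0.142, 0.163, 0.104, 0.0945 and 0.0509. The peroxisomal and cytokine lists differed about as much with vehicle, though neither passed there (camera adjusted p = 0.155 and 0.0746). The mean log2 changes were -0.276 with vehicle and -0.261 with LPS for the peroxisomal list. For the cytokine list they were 0.428 and 0.302. The mean changes of the other lists named here were larger in size with LPS.

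Single genes of the glucose and fasting panel differed between genotypes under LPS, in both directions, while no carbohydrate list passed. Of the gluconeogenesis genes 6 of 16 were higher and 3 lower (6 and 3 adjusted over the list alone; camera adjusted p = 0.462). Of the glycogen genes 3 of 15 were higher and 3 lower (4 and 4 adjusted over the list alone; 0.68). Of the glycolysis genes 4 of 16 were higher and 2 lower (8 and 3 adjusted over the list alone; 0.0897). Slc2a2, which encodes the liver glucose transporter GLUT2, was 2.49-fold lower in MCAD-/- (67.4 against 27.0 units, log2 change -1.32 ± 0.23, SE; adjusted p = 0.000383). Gys2, the liver glycogen synthase, was 1.90-fold lower (361 against 190 units; adjusted p = 0.00238). Ppargc1a was 3.56-fold higher (23.2 against 82.4 units; adjusted p = 0.000493). Pck1, which makes phosphoenolpyruvate for gluconeogenesis, was 1.31-fold higher (adjusted p = 0.0404), Fbp1 1.18-fold higher (adjusted p = 0.0457) and Cpt1a, the gate of fatty acids into mitochondria, 1.41-fold lower (adjusted p = 0.0391). G6pc (log2 change -1.36 ± 0.59, SE; adjusted p = 0.109), Pklr (-0.94; 0.0531), Pdk4 (-1.26; 0.158), Pygl (-0.29; 0.198) and Pcx (0.11; 0.474) did not pass. The calls of Pck1, Fbp1, Cpt1a, Zfp36, Gpam and Oat ended in at least 1 alternative, with a highest adjusted p of 0.32, 0.0931, 0.204, 0.138, 0.0872 and 0.0566, and Pklr, G6pc, Pdk4 and Pygl passed in 5, 2, 2 and 1 alternatives.

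The largest differences under LPS included Ugt2b38 (at least 24.6-fold higher in MCAD-/-), Olig1 (55.5-fold), Acpp (24.4-fold), Rpgrip1 (at least 16.5-fold), Efhd2 (17.8-fold), the protease inhibitor A2m (16.4-fold) and Unc45b (at least 7.72-fold). On the lower side were Xaf1 (at least 44.1-fold), Zfp874a (at least 17.7-fold), Cap1 (at least 15.5-fold), Gm7969 (at least 15.2-fold), Abhd1 (at least 10.4-fold), Acadm and Cidec; a second probe set of Xaf1 was past the threshold in the opposite direction. In all 1806 genes passed the threshold, 768 higher and 1038 lower, and 997 had groups that did not overlap. With each array centred on its median, 875 were higher and 947 lower. Without MCAD-/- LPS replicate 3, the mouse with the highest Acadm reading in its group, 5 lists in place of 9 passed the threshold. Across the 2 injections, 565 genes were past the threshold in the same direction, 280 higher and 285 lower, where independent lists would share 75.4 and 66.4, and 28 went opposite ways. Over all genes the 2 genotype effects correlated with Pearson r = 0.585 and Spearman rho = 0.431, across genes, which are not independent replicates.

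**Figure D2:**
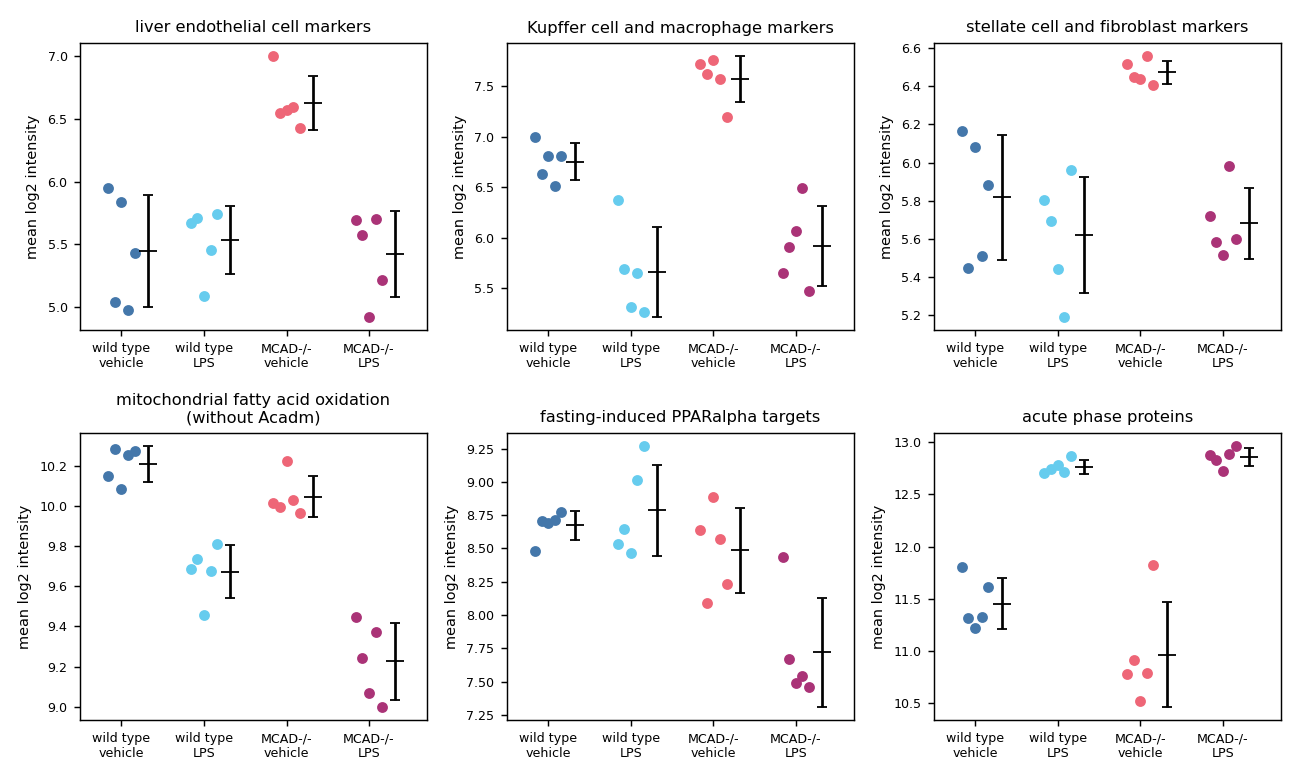
Mean log2 intensity (y axis, a different range in each panel) over the measured members of 6 gene lists in each mouse, by group on the x axis; points are mice, n = 5 per group, and the black mark with bars is the mean ± SD. The endothelial markers average 6.63 in MCAD-/- mice with vehicle and between 5.42 and 5.53 in the other 3 groups, and the mitochondrial fatty acid oxidation genes are lowest, at 9.23, in MCAD-/- mice with LPS.

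With LPS, 64% of the tested genes passed the threshold in wild type mice. Of these, 1235 were at least 2-fold higher and 773 at least 2-fold lower. All 15 tested cytokine and NF-kappaB target genes and 27 of 28 tested interferon-stimulated genes rose, with medians of 2.19 and 2.28 on the log2 scale. Each of these lists named 32 genes. The neutrophil list named 16, with 5 tested, and the LPS sensing list 16, with 13 tested. A gene at the floor with vehicle was tested only if it was high with LPS, so its rise was largely set by the filter. The calls of these lists held in all 16 other settings with the preset correlation, among them no filter. The chemokine Ccl5 was at least 19-fold and Cxcl13 at least 12.6-fold higher, the NF-kappaB inhibitor Tnfaip3 at least 2.61-fold, Irf7, a regulator of interferon genes, 33.8-fold and Gbp3 43.8-fold. The LPS co-receptor Cd14 was at least 107-fold higher, and 11 of 13 LPS sensing and tolerance genes rose. Of the acute phase proteins 21 of 25 rose, led by Saa3 (123-fold, to 14590 units) and Il1rn (25.2-fold), and 5 of 5 neutrophil markers rose, with S100a9 85.1-fold higher. The largest rises also included Gbp2b (at least 74.1-fold), Cxcl9 (317-fold), Reg3b (226-fold), Gbp2 (at least 48.6-fold) and Reg3g (at least 25.2-fold).

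Metabolic genes fell in wild type mice given LPS. Of the bile acid genes 14 of 17 fell, with Cyp7a1, the rate-limiting enzyme of bile acid synthesis, 182-fold lower and Akr1d1 21.8-fold lower. Of the oxidative phosphorylation subunits 28 of 32 fell by a median of 0.39 on the log2 scale, and 17 of 23 genes of pyruvate dehydrogenase and the citric acid cycle fell and 1 rose, with Dlat 4.99-fold lower. Of the mitochondrial fatty acid oxidation genes 16 of 20 fell (Hadh 3.45-fold lower), of the peroxisomal ones 12 of 16 fell and 1 rose (Decr2 6.69-fold lower), and of the fatty acid synthesis genes 14 of 17 fell and 1 rose (Acss2 5.63-fold lower). Drug-metabolising enzymes (15 of 18 lower, 1 higher; Cyp3a25 6.74-fold), amino acid catabolism (15 of 20 lower, 1 higher; the proline oxidase Prodh 9.89-fold) and growth hormone and sex-biased genes (10 of 14 lower; Hsd3b5 at least 75.8-fold) fell too. Cholesterol synthesis went the other way, with 14 of 20 higher and 2 lower, among them Hmgcs1 (4.79-fold) and Lss (3.85-fold). Other large falls were Klb, the co-receptor of fasting and bile acid hormones (at least 12.0-fold), Hsd3b2 (at least 10.5-fold), Acot3 (at least 9.77-fold), Keg1 (51.2-fold) and Rgs16 (45.2-fold).

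Genes of glucose release and glycogen fell in wild type with LPS, while of the glycolysis and glucose uptake list 9 of 16 rose and 4 fell (9 and 5 adjusted over the list alone; camera adjusted p = 0.782). Slc2a2 was 37.7-fold lower with LPS (2539 to 67.4 units; log2 change -5.24 ± 0.23, SE; adjusted p = 3.34e-13), Pklr 7.23-fold, G6pc, the last enzyme of glucose release, 6.52-fold, Gys2 5.39-fold, Pygl 4.09-fold and Pck1 1.55-fold lower, all past the threshold. Of the gluconeogenesis list 11 of 16 fell and 2 rose (Slc37a4 2.43-fold lower), and of the glycogen list 9 of 15 fell and 4 rose (Ppp1r3b 5.64-fold lower, the glycogenin Gyg 3.01-fold higher). Pdk4, which restrains pyruvate dehydrogenase, rose 7.95-fold (adjusted p = 0.000285), and Cpt1a fell 1.73-fold. Fbp1 was 1.24-fold higher, a call that ended when each array was centred on its median (adjusted p = 0.127). Ppargc1a was 1.83-fold lower (adjusted p = 0.0252), and its log2 change went from -0.87 to -0.49 (adjusted p = 0.0826) without wild type LPS replicate 2, which read 8.01 units. Pcx (log2 change -0.14) and Fgf21 (0.03) did not pass. Pcx passed in 3 alternatives, with a log2 change of -0.30 when each array was centred on its median (adjusted p = 0.0116). Markers of cells also moved: 7 of 12 Kupffer markers fell and 1 rose (Vsig4 at least 9.37-fold lower, Marco at least 14-fold higher), and 8 of 13 hepatocyte markers fell (Rbp4 1.82-fold).

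Of 32 lists, 19 passed in wild type with LPS, 6 up and 13 down, with camera adjusted p from 5.21e-11 to 0.0378, and 6 of them kept the call with an estimated correlation: oxidative phosphorylation, pyruvate dehydrogenase and citric acid cycle, bile acids, drug-metabolising enzymes, cytokines, and LPS sensing. For those that did not, the adjusted p with an estimated correlation was 0.0515 for glycogen, 0.0626 for interferon-stimulated genes, 0.0629 for amino acids, 0.0846 for peroxisomal oxidation and for growth hormone genes, 0.0866 for gluconeogenesis and 0.108 for neutrophils. It was 0.115 for fatty acid synthesis, 0.157 for hepatocytes, 0.193 for mitochondrial oxidation, 0.379 for the acute phase and for Kupffer cells, and 0.64 for cholesterol. Adjusted over the list alone, the counts differed from those above by 1 member in the glycogen (10 lower), oxidative phosphorylation (29 lower) and drug-metabolising lists (16 lower). The cholesterol call ended in 7 of 16 other settings (highest adjusted p 0.111). In all, 5614 of 8774 genes passed the threshold, 3507 higher and 2107 lower. LPS moved the median of all genes by 0.18 on the log2 scale in wild type and 0.14 in MCAD-/-, so levels are relative to that shift; with each array centred on its median, 2760 genes were higher and 2662 lower in wild type.

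MCAD-/- mice responded to LPS over a similar set of genes. The LPS changes of the 2 genotypes correlated with Pearson r = 0.902 and Spearman rho = 0.876 over all genes, and 4576 genes passed in the same direction in both, 2777 higher and 1799 lower (1336.6 and 582.1 for independent lists), against 25 in opposite directions. In MCAD-/- 27 of 28 interferon-stimulated genes, 13 of 15 cytokine genes (1 fell), 23 of 25 acute phase genes, 10 of 13 LPS sensing genes and 5 of 5 neutrophil markers rose. The limit that the filter sets on such counts holds here too. Ccl5 was at least 23.8-fold, Gbp2 at least 34.8-fold, Cd14 152-fold, Il1rn 80.6-fold and Steap4 8.59-fold higher. Reg3b (894-fold), A2m (795-fold), Tifa (168-fold), S100a8 (135-fold), Crybb3 (at least 66-fold) and Reg3g (at least 27.6-fold) were the other largest rises. Reg3b, A2m, Tifa and S100a8 exceeded 16 units in only 1 of 5 vehicle mice (group means 6.84, 8.76, 12.2 and 10.1 units), so their sizes and order depend on the floor of the values. Of the unfolded protein and stress response genes 15 of 24 rose and 3 fell, with the stress transcription factor Ddit3 9.56-fold and the chaperone Calr 2.10-fold higher, and of the immediate early genes 6 of 10 rose, with Ier3 at least 31.1-fold and Junb 7.92-fold higher.

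The metabolic falls were also seen in MCAD-/- mice with LPS. Slc2a2 was 69.3-fold lower (1874 to 27.0 units; adjusted p = 3.59e-14), G6pc 23.7-fold, Gys2 12.5-fold, Pklr 8.37-fold, Pygl 3.54-fold, Cpt1a 2.05-fold and Pck1 1.46-fold lower, Fgf21 was at least 1.06-fold lower, with group means of 17 and 4.59 units, and Pcx was 1.39-fold higher. Pdk4 did not pass (log2 change 1.03; adjusted p = 0.147), Ppargc1a was 1.74-fold lower (adjusted p = 0.0388, and 0.117 without MCAD-/- vehicle replicate 4), and Fbp1 was 1.18-fold higher, with adjusted p = 0.158 when each array was centred on its median. The G6pc fold leaned on MCAD-/- LPS replicates 3 and 5, which read 22.65 and 36.2 units. The other mice of that group read 145.9 to 442.6 units, near the 153.7 to 427 units of wild type with LPS. Pklr read 11.33 to 16.41 units in that group apart from replicate 5 (45.39), so its fold depends on the floor. Of the mitochondrial fatty acid oxidation genes 19 of 20 fell (Hadh 4.80-fold), of the bile acid genes 15 of 17 fell and 1 rose (Cyp7a1 at least 130-fold lower, Abcb4 7.14-fold), of the oxidative phosphorylation subunits 29 of 32 fell. Of the cholesterol synthesis genes 16 of 20 rose and 1 fell (Lss 6.59-fold). Of the gluconeogenesis list 10 of 16 fell and 2 rose (Gpd1 7.06-fold lower), of the glycogen list 9 of 15 fell and 4 rose (Ugp2 3.82-fold lower), and of the citric acid cycle list 17 of 23 fell and 2 rose (Suclg1 2.17-fold lower). Endothelial (9 of 15 lower, 2 higher; Clec4g 52.2-fold lower, Ptprb 9.97-fold), Kupffer (10 of 12 lower, 1 higher; Vsig4 at least 22.7-fold lower) and stellate markers (7 of 13 lower; Reln 2.85-fold) fell, as did 10 of 13 hepatocyte markers (Rbp4 2.15-fold).

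The remaining lists past the threshold in MCAD-/- with LPS were peroxisomal oxidation (13 of 16 lower; Acaa1b 5.36-fold), fatty acid synthesis (12 of 17 lower, 1 higher; Dgat2 8.12-fold lower), drug-metabolising enzymes (16 of 18 lower, 1 higher; the receptor Nr1i3 21.5-fold lower), amino acid catabolism (15 of 20 lower, 3 higher; Prodh 8.77-fold lower) and growth hormone genes (9 of 14 lower, 2 higher; Hsd3b5 at least 95.8-fold lower). With an estimated correlation these 5 had adjusted p = 0.0876, 0.174, 0.0434, 0.163 and 0.174. Other large falls were Hsd3b2 (at least 25.1-fold), Rgs16 (at least 27.4-fold) and Clec2h (at least 12.6-fold). Of 32 lists 23 passed, 8 up and 15 down, with camera adjusted p from 8.91e-11 to 0.0379, and 5 kept the call with an estimated correlation: oxidative phosphorylation, bile acids, drug-metabolising enzymes, cytokines and LPS sensing. For those not yet given the adjusted p with an estimated correlation was 0.0504 for the citric acid cycle, 0.0759 for interferon-stimulated genes, 0.0876 for glycogen, 0.09 for neutrophils, 0.128 for mitochondrial oxidation and for gluconeogenesis, 0.174 for hepatocytes, and 0.211 for the acute phase, the stress response and Kupffer cells. It was 0.274 for stellate cells, 0.314 for cholesterol, 0.352 for immediate early genes and 0.396 for endothelial cells. Adjusted over the list alone, 11 gluconeogenesis, 13 fatty acid synthesis and 11 Kupffer members fell and 4 amino acid members rose, and the other counts were equal. The calls of the immediate early, stellate and stress response lists ended in 2, 1 and 1 of 16 other settings (highest adjusted p 0.0925, 0.379 and 0.0605). In all, 5768 genes passed the threshold, 3344 higher and 2424 lower; with each array centred on its median, 2833 were higher and 2734 lower.

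The interaction asked which genes responded to LPS differently in the 2 genotypes. Cidec rose from 9.19 to 432 units in wild type and from 6.60 to 15.5 units in MCAD-/-, an interaction of -4.32 ± 0.44 on the log2 scale (SE; adjusted p = 5.06e-06). Gys2 fell from 1947 to 361 units in wild type and from 2374 to 190 units in MCAD-/- (interaction -1.22 ± 0.28; adjusted p = 0.0173). Pcx was 1727 and 1561 units in wild type and rose from 1214 to 1690 units in MCAD-/- (interaction 0.62 ± 0.15; adjusted p = 0.0187). The interaction of Fgf21 also passed (adjusted p = 0.0309), with 16.5, 16.9 and 17 units in the other groups and all 5 MCAD-/- mice with LPS under 16 units, so that its size depends on the floor. The nuclear receptor Nr0b2, a repressor of bile acid synthesis, was 194 and 140 units in wild type and fell from 218 to 15.9 units in MCAD-/- (interaction -3.31 ± 0.78; adjusted p = 0.0187). The interactions of Slc2a2 (-0.88; adjusted p = 0.13), G6pc (-1.86; 0.218), Pdk4 (-1.96; 0.213), Pck1, Fbp1, Pklr, Pygl, Cpt1a and Ppargc1a did not pass.

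Of the endothelial markers 7 of 15 had a more negative LPS response in MCAD-/- (12 adjusted over the list alone), with a median interaction of -1.48. In wild type and MCAD-/- these markers averaged 5.45 and 6.63 with vehicle and 5.53 and 5.42 with LPS on the log2 scale. The genotypes thus differed mainly with vehicle. The list passed camera (adjusted p = 1.1e-08), and had adjusted p = 0.734 with an estimated correlation. Among them were Clec4g (-1.95), Tek (-2.00) and Kdr (-2.12), receptors of vascular growth signals in the last 2 cases. Stellate markers did so in 2 of 13 (2 adjusted over the list alone), Pdgfrb (-1.63) and Angptl6 (-0.78), and PPARalpha targets in 2 of 16 (5 adjusted over the list alone), Cidec and Fgf21. In the cholesterol list 1 of 20, Cyp51 (1.47), had a more positive response (4 adjusted over the list alone). No member of the mitochondrial fatty acid oxidation (median -0.30), amino acid (0.15) or acute phase list (0.27) passed on its own in limma, nor did any adjusted over the list alone, with 10, 3 and 8 members at an unadjusted p under 0.05, while the lists passed camera (adjusted p = 0.0251, 0.0171 and 2.31e-05). The cholesterol, PPARalpha and stellate lists had camera adjusted p = 5.93e-06, 0.0032 and 0.0215, and all 7 lists had adjusted p = 0.734 with an estimated correlation. The calls of the mitochondrial oxidation, stellate and amino acid lists ended in 8, 3 and 1 of 26 other settings (highest adjusted p 0.11, 0.345 and 0.108). The stellate and acute phase lists also differed between genotypes mainly with vehicle. In wild type and MCAD-/- the stellate list averaged 5.82 and 6.47 with vehicle and 5.62 and 5.68 with LPS. The acute phase list averaged 11.45 and 10.96 with vehicle and 12.76 and 12.86 with LPS.

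The other interactions named by size each involve at least 1 group that averaged under 16 units, as does that of Cidec, so that their sizes and order depend on the floor of the values. Among them, Olig1 (5.40), A2m (3.43) and the antimicrobial lectin gene Reg3a (3.18) rose more with LPS in MCAD-/-, A2m from 8.76 to 6967 units there and from 5.77 to 424 units in wild type. Myom2 (4.66), Trhde (3.32), Aqp4 (3.29) and Lrit1 (3.22) fell with LPS in wild type and lay under 16 units on average in both MCAD-/- groups. On the negative side were Clec2h (-6.15), which fell with LPS in MCAD-/- and was under 16 units in wild type, Sgk2 (-2.97), Dntt (-2.89), Igdcc4 (-2.87) and Xaf1 (-2.68). In all, 361 genes passed, 119 above 0 and 242 below, while 1744 had an unadjusted p under 0.05; with each array centred on its median 155 lay above 0 and 194 below. The calls of Fgf21, Cyp51, Reg3a and Angptl6 ended in at least 1 alternative (highest adjusted p 0.061, 0.0833, 0.0744 and 0.0597), and that of Xaf1 ended, with the sign turned, under the mean of its probe sets.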

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

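The 2 tests of the fatty acid oxidation pattern, the tests of whether 3 cell types rose alike, which was made a separate explanation only once its values were known, the Kupffer and stellate relations with the acute phase, and the probe set comparisons without a threshold were chosen after the result was seen. Interactions were tested in limma, as the difference between the 2 LPS responses. They passed the threshold for 361 genes, and with the preset correlation for 7 lists, each of which had adjusted p = 0.734 with an estimated correlation. The medians of these lists were -0.297 (mitochondrial fatty acid oxidation), -0.456 (PPARalpha targets), 0.564 (cholesterol synthesis), 0.152 (amino acid catabolism), 0.269 (acute phase), -1.484 (endothelial) and -0.604 (stellate). The named genes were Olig1 (5.40), Myom2 (4.66), A2m (3.43), Trhde (3.32), Aqp4 (3.29), Lrit1 (3.22), Reg3a (3.18), Cyp51 (1.47) and Pcx (0.62) above 0. Below 0 were Clec2h (-6.15), Cidec (-4.32), Nr0b2 (-3.31), Sgk2 (-2.97), Dntt (-2.89), Igdcc4 (-2.87), Xaf1 (-2.68), Kdr (-2.12), Tek (-2.00), Clec4g (-1.95), Fgf21 (-1.92), Pdgfrb (-1.63), Gys2 (-1.22) and Angptl6 (-0.78). Apart from Cyp51, Pcx, Kdr, Pdgfrb and Gys2, each of these genes averaged under 16 units in at least 1 group, so the sizes and their order depend on the floor of the values.

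Single mice stood far from the other 4 of their group in 18 of 188 groups of values, where chance gives about 1 in 20. In wild type with vehicle, replicate 3 was lowest for Fbp1 (12.65 on the log2 scale), for the glycolysis list mean (7.44) and for the stress response list mean (7.53), and highest for Pklr (8.37). Replicate 1 of that group was lowest for Pygl (11.73), Fgf21 (2.88), the PPARalpha target mean (8.48) and the growth hormone list mean (9.20). In wild type with LPS, replicate 4 was highest for the actin 3' to 5' log2 ratio (3.69) and the pentose phosphate list mean (9), and replicate 5 was highest for the drug-metabolising list mean (9.85) and the stress response list mean (8.81). In MCAD-/- with vehicle, replicate 5 was highest for the neutrophil marker mean (5.87) and replicate 3 for the mitochondrial fatty acid oxidation mean (10.22). In MCAD-/- with LPS, replicate 3 was lowest for Pck1 (12.22) and the fatty acid synthesis mean (7.57), replicate 5 highest for Pklr (5.50) and replicate 1 highest for the PPARalpha target mean (8.43).

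Endothelial, Kupffer and stellate markers were all higher in MCAD-/- mice with vehicle. An acute phase reaction in the wild type vehicle mice that lowers them stays open, as the relation within groups over 20 arrays was too imprecise: acute phase and endothelial means had Pearson r = 0.035 with a jackknife error of 0.36 (permutation p = 0.873; Spearman rho = 0.101, p = 0.691), Kupffer means r = -0.303 with 0.27 (p = 0.0854; rho = -0.325, p = 0.129) and stellate means r = 0.147 with 0.30 (p = 0.386; rho = 0.195, p = 0.401). A lower share of hepatocyte RNA that raises all 3 cell types alike stays open too. The endothelial and stellate medians lay 0.50 apart (standard error 0.23 over list members), under the 0.53 needed for the widest of 3 gaps. However, the gap of the list means per mouse was 0.52 (exact permutation p = 0.00794, the smallest that 252 regroupings allow). That exact p was 0.0238 adjusted over 3 gaps and goes against a like rise. The hepatocyte markers did not fall in that comparison (0 of 13 lower, 1 higher, median log2 change 0.015). A loss of share too small to show in them was not tested. A larger share of RNA from these cells that need not be equal between types stays open too, and may account for it: within groups the 3 list means rose and fell together (mean r = 0.519, permutation p = 0.00031; 0.00124 after adjustment for the 4 relations tested). No control lists were correlated in this way. A factor common to whole arrays could also make the 3 list means move together, so their correlation does not single out a share of RNA. A change of expression within these cells with the genotype stays open too, as untested.

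Genotype changed 565 genes in the same direction under both injections. Acadm left out, 177 of them changed at least 2-fold in both. A passenger segment around Acadm could not account for most of them: 5 of 562 lay within 20 Mb of it (0.89%, against 0.659% of other tested genes; odds ratio 1.35, Fisher exact p = 0.428), which were Cth, Ddah1, Ifi44l, Lmo4 and Manba, named after their values were seen. Segments of SV129 or BL6 origin elsewhere remain a candidate explanation: 59.2% of the genes outside that window had another such gene within 1 Mb, above the 95th percentile of random sets (57.8%, median 53.9%), a small excess that clustered gene families could also give. Sequence variants under the probes may account for part, because all probe sets were past the threshold the same way in 45.1% of 51 such genes with a 2-fold change, against 83.2% of 543 genes changed by LPS (Fisher exact p = 6.44e-09). Without a threshold the gap was narrower, at 80.4% against 93.2% for all probe sets in the same direction (Fisher exact p = 0.00396) and 45.1% against 72.7% for at least 50% of the log2 change in each (p = 8.59e-05), 3 of the 51 genes had a probe set past the threshold the other way, and the loss of MCAD itself stays open for any of these genes.

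Fatty acid oxidation genes were lower in MCAD-/- mice under LPS. A lower share of hepatocyte RNA was argued against only as far as the hepatocyte markers show it. Their median change lay 0.40 above that of the oxidation list, with a standard error of 0.09. That error was taken over list members, which can vary together, and not over mice, so it may be too small. Per mouse, these markers averaged 12.97 ± 0.12 in wild type and 13.02 ± 0.1 in MCAD-/- with LPS (SD, log2 scale). The oxidation list averaged 9.67 ± 0.13 and 9.23 ± 0.19. Whether markers this bright would show a modest loss of share was not tested. A stronger LPS response overall stays open: over 2732 genes that fell in either genotype the slope of the LPS changes in MCAD-/- on those in wild type, with error allowed in both, was 1.13 with a jackknife error of 0.08, and the list itself needs 1.54, a difference of 0.41 with a jackknife error of 0.39. The list kept its call with each array centred on its median and in the 15 other settings run with the preset correlation, but not with an estimated correlation (adjusted p = 0.591), and GCRMA itself could not be rerun from these values. That the genotype lowers these genes more during LPS remains a hypothesis, since the interaction of the list had adjusted p = 0.734 with an estimated correlation.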

How the results depend on the processing

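Leaving out 4 arrays that stood apart was chosen after seeing the data (wild type vehicle replicate 3, wild type LPS replicate 4, MCAD-/- LPS replicate 3 and MCAD-/- vehicle replicate 5). Counts of genes stayed within 1.5 times under the alternatives except these: array weights gave 2855 genes for genotype under vehicle and 879 for the interaction, an added 1.5-fold minimum gave 1100 for genotype under LPS, and the stricter filter gave 236 for the interaction, with fewer genes tested. Lists past the threshold fell to 0 for both genotype comparisons and the interaction, to 6 for LPS in wild type and to 5 in MCAD-/- with an estimated correlation. For genotype under LPS 5 lists were left with the mean of all probe sets and 5 without the 4 arrays, and 5 to 11 when single mice were left out; the cause was not tested. The similarity of the LPS response moved from 0.902 to 0.886 with no filter and 0.923 with the stricter filter. The interaction of Xaf1 turned from -2.68 to 0.43 (adjusted p = 0.257) under the mean of its probe sets, which disagree. An added 1.5-fold minimum ended the calls of Fbp1 in the 4 group comparisons, Pcx for genotype under vehicle and for LPS in MCAD-/-, and Pck1 for genotype under LPS and for LPS in MCAD-/-, among others. Without single mice the genes ran from 1045 to 1397 and 1371 to 1765 for genotype under vehicle and LPS, and from 262 to 468 for the interaction. Mice were not treated as paired, as not every same-number correlation exceeded 0.1 in any comparison (range -0.121 to 0.284). For genotype under LPS 3 of 5 did, and 2 of 5 mice matched their own number best. That rule could not detect a pairing of only some mice. A replicate block gave 1397, 1845, 5619, 5796 and 384 genes and 6, 7, 19, 23 and 9 lists in the 5 comparisons, and the Fbp1 call for genotype under LPS had adjusted p = 0.07. Of the genes named, 34 of 44, 38 of 51, 72 of 77, 82 of 87 and 28 of 33 kept direction and side of the threshold under all alternatives run. Signal near the floor limits genes under 16 units.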

Other observations

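The tests reported here were set before the result was seen, while the lists named next were picked from those tested after their values were seen. Some lists that did not pass camera still held genes that responded to LPS. Over all tested genes the share past the threshold for LPS was 64% in wild type and 65.7% in MCAD-/-. Such members therefore do not set a list apart. Of the glycolysis and glucose uptake genes 9 of 16 rose and 4 fell with LPS in wild type (9 and 5 adjusted over the list alone; list adjusted p = 0.782), and 11 rose and 4 fell in MCAD-/- (11 and 4 adjusted over the list alone; list adjusted p = 0.228). Of the circadian clock genes 2 of 12 rose and 5 fell in wild type (2 and 5 adjusted over the list alone; list adjusted p = 0.102), and 4 rose and 7 fell in MCAD-/- (4 and 7 adjusted over the list alone; list adjusted p = 0.0801). Of the bile acid genes 6 of 17 were lower and 1 higher in MCAD-/- than in wild type under LPS (7 and 1 adjusted over the list alone; list adjusted p = 0.0897). Among the 361 genes with an interaction, 85 were induced in wild type and less or not in MCAD-/-, 88 were induced more in MCAD-/-, 136 were repressed more there and 19 were repressed less or not, and 25 of the genes counted here moved in opposite directions in the 2 genotypes.

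Other splits of the same mice were tested as a check on chance. For genotype under vehicle, 1 of 100 splits of the 10 mice, the real one, called as many genes as the real 1422, and the highest other called 187. For genotype under LPS it was 1 of 100, with 1806 genes against 540. For LPS in wild type it was 1 of 100 with 5614 against 1983, and in MCAD-/- 1 of 100 with 5768 against 3105. For the interaction, 1 of 100 regroupings of genotype within each injection reached 361 genes, and the highest other reached 101. In the group comparisons no other split drawn reached the real count, which argues against chance regrouping there. For the interaction, regrouping also broke up the genotype difference within each injection. Such regroupings could call fewer genes even without an interaction, so they cannot exclude chance for the 361 genes.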
